A study of Mus musculus with 3 samples.

How the data were processed

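Single-cell 3' libraries of mouse liver HSC suspensions were analysed, 1 library each for the Oil, CCL4 and BDL groups, which were taken from the agent in the sample characteristics. The matrices hold raw UMI counts per gene and barcode as deposited by the authors, made with Cell Ranger software version 3.0.2 per the file headers. Per the submitters' processing notes, Cell Ranger 3 and Seurat were used and the build was GRCm38; how cells were called and which annotation was used for counting were not given in the sources used here. The counts were not normalized by the authors per the file headers, and cover 31234 features, the same in the 3 libraries. The lowest barcode of each library had 500 UMIs. No cell annotation by the authors was used here.

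Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs, which passed 11943 of 13496 in Oil, 21588 of 24651 in CCL4 and 21005 of 27561 in BDL. Over 20% mitochondrial UMIs were found in 8.48%, 8.71% and 21.6% of barcodes. Doublets were called per library with scrublet as implemented in scanpy 1.11.5, at an expected 8.0%, and removed: 6.77%, 8.82% and 9.05% by its automatic threshold. The remaining cells were clustered together without integration, on 30 principal components of 2000 variable genes, with 15 neighbours and Leiden resolution 0.8 (leidenalg 0.10.2, igraph 0.11.9). Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. Markers of 15 cell classes were fixed before the data were examined, and the rule that scores them was set after the clusters had been seen. A marker counted as present when seen in at least 20% of a cluster's cells and at 10% or more of the highest cluster, and a cluster of at least 20 cells took the class of which it had the largest share of markers, if at least 50% and at least 3. A cluster was left unnamed as mixed if a class of another lineage also had at least 50% of its markers present. So was a cluster under 1% of all cells in which at least 3 markers, and at least 25%, of another lineage's class stood at 4 times or more the level of the other clusters of its own class, taken as at least 5 CPM. A named cluster whose 10 top genes held more markers of another class than of its own lost its name. So did a cluster with a median depth under 1 / 3 of its library and none of its own markers among those 10 genes.

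Cells are not replicates, and with 1 library per group no test was run. UMIs were summed over the HSC-like cells of each library and given as CPM with exact Poisson intervals, ratios as log2 with exact conditional binomial intervals, and shares with Clopper-Pearson intervals, all at 95%. Where a group had 0 UMIs, the fold is a lower bound against a floor of 3 UMIs over the class. The comparisons were CCL4 against Oil, BDL against Oil and BDL against CCL4. The 2 comparisons with Oil share that library, so no overlap or correlation between them was computed. The median log2 ratio of each of 19 gene lists, fixed before the data were examined, was taken over members with at least 100 UMIs in the 2 libraries together, with an order-statistic interval over members and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. To compare shares of cells, each cell was thinned to 2000 UMIs and shallower cells were left out. Beside each share stands that of endothelial-like cells. Free RNA in the droplets was estimated from markers of hepatocytes, macrophages, T and NK cells, B and plasma cells, neutrophils and erythroid cells as 13.2%, 13.8% and 10.6% of the HSC-like sums. This is a median over 37, 50 and 51 genes that differ widely, and it was subtracted in an alternative only. Similar medians do not mean similar free RNA of each cell type. The hepatocyte gene Ttr stood at 37.6, 225.7 and 23.2 CPM in HSC-like cells of Oil, CCL4 and BDL. In endothelial-like cells it stood at 49.9, 759.2 and 51.7 CPM.

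Genes were named by a rule fixed before the data were examined: in each comparison the 12 highest and 12 lowest log2 ratios in HSC-like cells among genes with at least 100 UMIs over the 2 libraries and at least 50 CPM in the higher one. Mitochondrial, ribosomal protein, predicted, haemoglobin, Xist and Y-linked genes were left out, as were genes whose CPM was under 1 / 4 of that in another named class of at least 50 cells. The 4 members of each list with the largest ratios past the same filters, and a fixed set of 15 HSC, matrix and contractile genes, were named as well. As exceptions beyond the written rule, EGFP, tdTomato, mitochondrial ribosomal protein genes and Tsix were also left out of the ranking, and the class markers Pdgfrb, Des and Hgf and the gene Pdgfra were added to the fixed set. EGFP, tdTomato, Ifi202b in other classes and the sex-linked genes were chosen after their values were seen. Gene positions come from GENCODE release M21 on GRCm38, where 170 of 170 named genes matched by gene ID.

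The ratio and interval code was tested on simulated counts drawn from the means and totals of these libraries, with genes set to known folds. The intervals held the true ratio for 95.5% of 12160 unchanged genes for CCL4 against Oil, 95.25% of 12001 for BDL against Oil and 94.9% of 12940 for BDL against CCL4, and for 86.0% or more of the genes in each group of a changed fold, the lowest being 4-fold genes in BDL against Oil. For genes set to 4-fold the median log2 ratio was 1.98, 1.98 and 1.97. The alternatives were a stricter cell filter (1000 genes, 10% mitochondrial UMIs), doublets kept, resolution 1.5, median-of-ratios scaling, the mean over cells, thinning to 2000 or 4000 UMIs, subtraction of free RNA, adding fibroblast-like and smooth muscle-like cells, and a minimum of 20 UMIs. Adding cluster 6 to the HSC-like cells was chosen after seeing the data.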

Results

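Freshly isolated suspensions of mouse hepatic stellate cells (HSC), the pericyte-like liver cells that store vitamin A, were profiled by droplet single-cell RNA sequencing with 3' kit chemistry version 3. The series held 3 libraries, 1 per group. The Oil library came from animals given corn oil, the CCL4 library from animals given the agent the labels call CCL4, and the BDL library from animals with a bile duct ligation. The title of the series names HSC activation and the origin of myofibroblasts in liver fibrosis as its subject. Dose, time, strain, number of animals and any reporter construct were not given in the sources used here. The matrices held 13496, 24651 and 27561 barcodes with 69121918, 211432898 and 179914935 UMIs for Oil, CCL4 and BDL. The median depth was 4614, 7737 and 4935 UMIs per barcode. After filters and doublet removal 11135, 19684 and 19103 cells were kept. With 1 library per group there was no replicate check and no test: every difference below is a difference between libraries, and the 95% intervals (exact Poisson for sums of UMIs, exact conditional binomial for ratios, Clopper-Pearson for shares) cover counting error only.

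Mesenchymal, endothelial, biliary and immune cells were all present in the suspensions. HSC-like cells made up 54.7% of the Oil cells (53.8 to 55.7), 53.2% of the CCL4 cells (52.5 to 53.9) and 46.5% of the BDL cells (45.7 to 47.2). Endothelial-like cells made up 25.9%, 7.15% and 22.8%, cholangiocyte-like cells 12.3%, 3.97% and 2.62%, and macrophage-like cells 0.916%, 8.61% and 9.71%. Mesothelial-like cells held 1.46%, 7.68% and 1.61%, dendritic-like cells 0.629%, 3.27% and 0.974%, and T and NK-like cells 0.296%, 0.671% and 2.11%. Fibroblast-like cells were 0.575% of Oil (64 cells), 0.239% of CCL4 (47 cells) and 8.25% of BDL (1576 cells, 7.86 to 8.65). Smooth muscle-like cells were 0.251%, 0.157% and 0.717%. Hepatocyte-like cells made up 1.52% and 2.78% of CCL4 and BDL; those of Oil lay in a shallow cluster of 165 Oil cells (1.48%) that had 12 of 12 hepatocyte markers and lost its name for its depth. These shares describe suspensions enriched for HSC, so the isolation can set them.

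The cells fell into 41 clusters, most of them mainly from 1 library, which may reflect the library and not a cell type. In Oil, cluster 0 held 99.2% of the HSC-like cells. In CCL4, clusters 2, 4, 9 and 15 held 43.3%, 32.0%, 20.7% and 3.76%, and in BDL clusters 1, 7, 14 and 15 held 57.5%, 25.6%, 11.04% and 4.48%. Cluster 15 was led by cell cycle genes, with 18 cells of Oil, 394 of CCL4 and 398 of BDL, and held 1209 of the 1388 Mki67 UMIs of the CCL4 HSC-like cells and 3422 of the 3627 of BDL; in Oil, cluster 0 held 32 of 226. Cluster 6, with 2562 cells of CCL4, 3 of Oil and 5 of BDL, reached the naming threshold of no class (7 of 18 HSC markers, 6 of 13 fibroblast markers, 4 of 9 smooth muscle markers) and was kept out of all of them. Cluster 2 passed as HSC-like with 10 of 18 HSC markers against 5 of 13 fibroblast markers. Clusters kept unnamed held 2.95%, 13.5% and 1.96% of the Oil, CCL4 and BDL cells. Clusters with too few markers of any class made up 0.0359%, 13.1% and 0.0262%, clusters mixed between 2 classes 1.44%, 0.356% and 1.94%, and the shallow cluster with hepatocyte markers 1.48%, 0.0102% and 0%. The naming thresholds were set after the clusters had been seen, and a difference from the study may come from these rebuilt names. With clustering at resolution 1.5 the HSC-like share of CCL4 was 28.7% and its fibroblast-like share 35.8%, and 97.6% of the CCL4 cells of cluster 2 and all of those of cluster 6 took the fibroblast name.

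Levels below are UMIs summed over the HSC-like cells of a library, as CPM, UMIs of a gene over the total of the class, which was 35528328 UMIs in Oil, 102256909 in CCL4 and 87285828 in BDL. Acta2 (ENSMUSG00000035783) lies on chromosome 19 from 34241090 to 34255590 on the minus strand. Col1a1 (ENSMUSG00000001506) lies on chromosome 11 from 94936224 to 94953042 on the plus strand. Timp1 (ENSMUSG00000001131) lies on chromosome X from 20870166 to 20874735 on the plus strand. Lrat (ENSMUSG00000028003) lies on chromosome 3 from 82892579 to 82903973 on the minus strand. Ccl2 (ENSMUSG00000035385) lies on chromosome 11 from 82035571 to 82037453 on the plus strand. Cthrc1 (ENSMUSG00000054196) lies on chromosome 15 from 39076932 to 39087121 on the plus strand. These positions are on GRCm38. The median log2 ratio of all measured genes was -0.19 for CCL4 against Oil, -0.12 for BDL against Oil and 0.09 for BDL against CCL4, and 0.10, 0.08 and -0.01 under median-of-ratios scaling, so ratios near these shifts carry no direction. Hspa1a and Hspa1b, the Mup genes, Ifi202b, the Serpina3 genes and the H2 genes have near-identical copies, between which counting can split reads, and their values are uncertain to that extent.

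The comparison of CCL4 with Oil asks how HSC-like cells differ between the injured and the control liver. Contractile and matrix genes were higher in CCL4. Acta2, which encodes the actin of smooth muscle and of myofibroblasts, stood at 3456 against 23.4 CPM, log2 ratio 7.20, 7.11 to 7.30. Col1a1, a chain of type I collagen, stood at 5367 against 138 CPM, log2 ratio 5.28, 5.24 to 5.32. Timp1, an inhibitor of matrix metalloproteinases, stood at 1252 against 6.02 CPM, log2 ratio 7.70, 7.51 to 7.90. Genes of the vitamin A storing HSC were lower, with Lrat, the enzyme that esterifies retinol for storage, at 602 against 2634 CPM, log2 ratio -2.13, -2.14 to -2.12.

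Among the 12 genes with the highest ratios, Cthrc1, a secreted glycoprotein of remodelling tissue, had 131 CPM in CCL4 and 1 UMI in Oil, a ratio of 4641 with an interval from 832.8 to 183300.0. Col15a1, a collagen of basement membrane zones, stood at 378 against 0.591 CPM, log2 ratio 9.32, 8.71 to 10.01. Serpina3n, a serine protease inhibitor, had a log2 ratio of 9.26 (8.51 to 10.13) and Ltbp2, which binds elastic fibres, 8.40 (7.82 to 9.04). Ch25h, Zfp469, Plat (tissue plasminogen activator) and Ncam1 stood at 8.64, 8.43, 7.17 and 7.06. Ifi202b, an interferon-inducible gene whose expression is known to differ between mouse strains, had 51.2 CPM in CCL4 and 0 UMIs in Oil, at least 606-fold higher against a floor of 3 UMIs over the class. It had 0 UMIs in all 11135 kept Oil cells, against 9007 UMIs over the kept CCL4 cells and 7470 over those of BDL. Whether the libraries differ in genetic background was not tested, and such a difference would bear on every value given against Oil.

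The 12 lowest genes were led by Hhip, a hedgehog-binding protein, at 8.14 against 329 CPM, log2 ratio -5.34, -5.44 to -5.24. Angptl6 (-4.39), the ficolin Fcna (-4.25), Tmem56 (-4.14), the erythropoietin receptor Epor (-4.06) and the VIP receptor Vipr1 (-4.01) followed, then Dcdc2a (-3.95), the collectin Colec10 (-3.66), Ntm (-3.65), Adamtsl4 (-3.56), Disp2 (-3.56) and Calcrl (-3.38). Angptl6, Vipr1 and Colec10, like Lrat, Reln, Ngfr, Colec11 and Cxcl12, are among the markers that named the HSC class, and Dpt, Eln and Fbln2 among those of the fibroblast class, so their levels partly decided which cells entered the comparison.

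Of the 21 measured genes of retinoid storage and quiescence, 16 were at least 2-fold lower and 0 at least 2-fold higher in CCL4 (median log2 -2.04, -2.42 to -1.09, below all random lists, where the interval is that of the median over members and the random lists are 10000 lists matched on mean expression). Reln, a secreted glycoprotein of resting HSC, stood at -2.42, Ngfr at -2.68 and Colec11 at -2.98; without its 11 class markers the list had a median of -1.11. Of 26 fibrillar collagen and interstitial matrix genes, 17 were at least 2-fold higher and 2 lower (median log2 1.39, 0.80 to 3.68, above all random lists), with Col3a1 at 2.92, Col12a1 at 6.44 and Mfap4 at 6.64. Of 20 contractile genes, 13 were higher and 0 lower (median log2 1.62, 0.61 to 3.16, above all random lists), among them Tagln at 4.23 and the tropomyosin Tpm2 at 3.16. Of 23 crosslinking and turnover genes, 15 were higher and 1 lower (median log2 1.25, 0.34 to 1.87, above all random lists), with the collagen-crosslinking oxidases Lox at 5.40 and Loxl1 at 3.31. These ratios are of sums over unlike clusters. Cluster 9, with 20.7% of the CCL4 HSC-like cells, had Ngfr at 198.3 CPM, against 256.0 in Oil. Clusters 2, 4 and 15 had Ngfr at 11.86, 22.59 and 42.06 CPM. Lox stood at 22.0 CPM in cluster 9 and at 290.5, 155.1 and 155.1 CPM in clusters 2, 4 and 15, against 4.98 in Oil.

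The S100, annexin and intermediate filament list had 8 of 15 genes at least 2-fold higher (median log2 1.08, 0.83 to 3.22, percentile 99.94), with S100a6 at 5.89 and Vim at 2.13. Secretory genes of the endoplasmic reticulum (ER) had 11 of 21 higher (median log2 1.07, 0.62 to 1.78, percentile 99.98), such as Kdelr3 at 3.32. The cell cycle list had 17 of 26 higher (median log2 1.24, 0.86 to 2.15, above all random lists), with Mki67 at 13.6 against 6.36 CPM and Tubb5 at 1.90. Glycolysis genes had 7 of 14 higher (median log2 1.03, 0.19 to 1.47, above all random lists). Dissociation and heat stress genes had 6 of 23 higher (median log2 0.65, 0.30 to 0.91, percentile 98.2), and this list also stood at 0.87 in endothelial-like cells. Chemokine and inflammatory genes had 13 of 28 higher and 2 lower (median log2 0.87, 0.10 to 2.09, above all random lists), with the chemokine Ccl7 at 2.85 and Cxcl12 at -2.23. Growth factors and receptors had 7 of 31 higher and 14 lower (median log2 -0.76, -2.04 to 0.45, percentile 0.13), with Igf1 at 5.50. Hgf, the hepatocyte growth factor and a class marker, stood at -1.71.

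The portal fibroblast list, 11 of whose 17 measured genes named classes, had 11 higher and 1 lower (median log2 2.60, 0.08 to 4.62, above all random lists; 1.98 without them), with Dpt at 5.78 and elastin, Eln, at 3.74. Basement membrane genes had 6 of 15 higher and 1 lower (median log2 0.71, -0.37 to 1.32, percentile 99.4). TGF-beta and YAP target genes had 4 of 16 higher and 2 lower (median log2 0.71, 0.06 to 2.39, percentile 99.8), with the matricellular protein gene Thbs1 at 3.66 and Tgfbi at -2.09. Cholesterol synthesis genes had 8 of 18 higher and 1 lower (median log2 0.56, -0.18 to 1.33, percentile 99.8). Oxidative and xenobiotic defence genes had 7 of 22 higher and 3 lower (median log2 0.27, -0.54 to 1.28, percentile 89.5), and interferon response genes 4 of 24 higher and 5 lower (median log2 0.06, -0.67 to 0.44, percentile 83.4). The pericentral HSC list of 7 genes had a median log2 of 0.50 (-2.04 to 3.31, percentile 88.9) and the periportal HSC list of 7 genes one of -1.27 (-2.96 to 4.23, percentile 0.52), the latter with Igfbp3 at -2.96 and Itgb3 at -2.47. Pdgfrb, Des and Postn, the first 2 of them class markers, stood at -0.04, 0.35 and 0.40.

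Of 93 named genes in this comparison, 47 moved by over 1.5 times under at least 1 alternative and 2, Pdgfrb and Wnt4, changed sign. Over all alternatives Ltbp2 ranged from 6.20 to 11.68, Dpt from 2.51 to 8.36, Mfap4 from 2.78 to 8.25, S100a6 from 3.57 to 6.19, Eln from 1.95 to 4.04 and Igf1 from 4.08 to 5.79; S100a6 was lowest with fibroblast-like and smooth muscle-like cells added and stood at 4.80 at resolution 1.5, where Eln and Igf1 were lowest. At resolution 1.5 Col1a1 stood at 4.34, Hhip at -4.39, the cell cycle median at 1.94, the periportal median at -0.59 and the pericentral median, turned, at -0.16. With the fibroblast-like and smooth muscle-like cells added, Acta2 stood at 5.57, Col15a1 at 6.13, Serpina3n at 6.66 and the portal fibroblast median at 0.92. With free RNA subtracted, Timp1 stood at 9.04, the growth factor median at -1.48 and the portal fibroblast median at 3.91, while the interferon median turned to -0.08 with cluster 6 added.

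**Figure D1:**
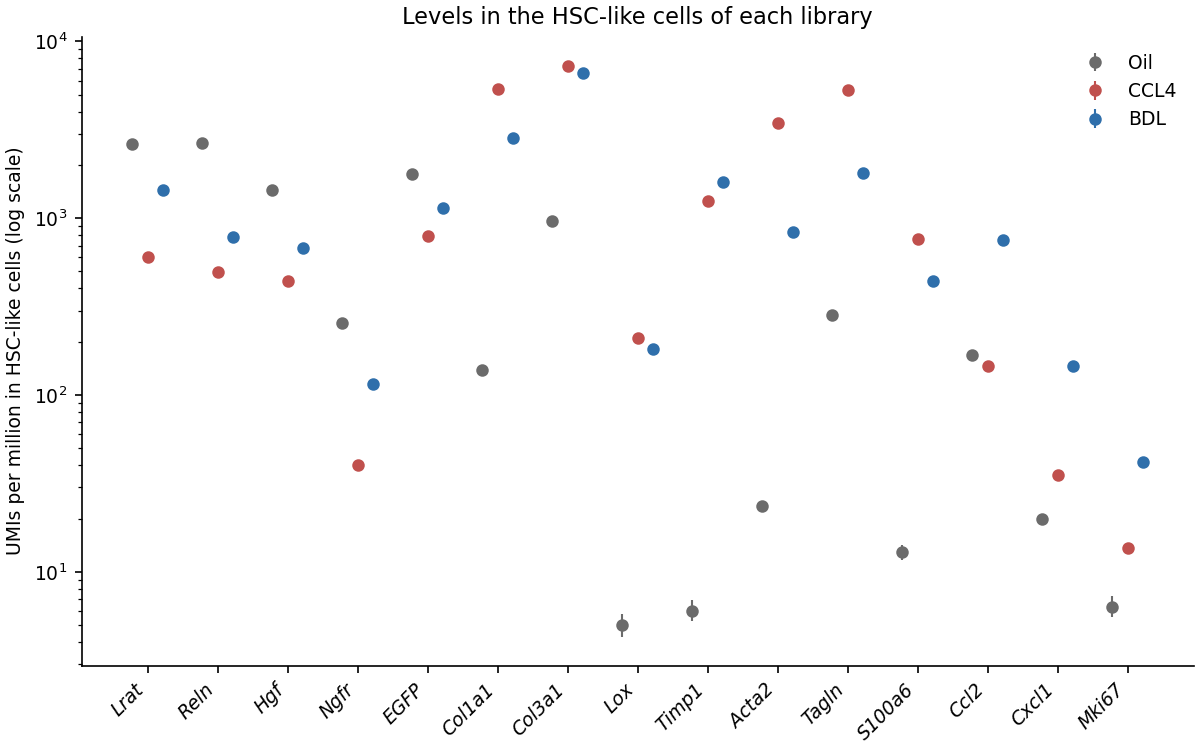
Levels of 15 genes in the HSC-like cells of each library, in CPM on a log scale, with 95% Poisson intervals of the sum as bars where they exceed the symbols. Acta2 stands at 23.4 in Oil, 3456 in CCL4 and 835 in BDL, and Lrat at 2634, 602 and 1443.

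The comparison of BDL with Oil asks the same of the liver after bile duct ligation; the labels give BDL no reference library of its own, so Oil served as one. Matrix, contractile and chemokine genes were higher in BDL. Timp1 stood at 1606 against 6.02 CPM, log2 ratio 8.06, 7.87 to 8.26, Col1a1 at 2850.1 against 138 CPM, log2 ratio 4.37, 4.33 to 4.41 and Acta2 at 835 against 23.4 CPM, log2 ratio 5.16, 5.06 to 5.26. Ccl2, a chemokine that recruits monocytes, stood at 750.2 against 169 CPM, log2 ratio 2.15, 2.11 to 2.19. The Ccl2 sum of BDL rested largely on cluster 7, at 1813 CPM, while cluster 1 stood at 156.8 CPM. Lrat was lower, at 1443 against 2634 CPM, log2 ratio -0.87, -0.88 to -0.86, and Reln at 781 against 2667 CPM, log2 ratio -1.77, -1.79 to -1.76.

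The highest genes included Ifi202b, with 55.4 CPM against 0 UMIs in Oil, at least 656-fold higher against the same floor. Fbn2, a fibrillin of elastic microfibrils, had 85.8 CPM against 3 UMIs, a ratio of 1017 (347.7 to 4931), and complement factor D, Cfd, 56.5 CPM against 2 UMIs, a ratio of 1004 (277.7 to 8289). Fbn2 was among the 10 top genes of cluster 14, with 11.04% of the BDL HSC-like cells. That cluster passed as HSC-like with 12 of 18 HSC markers against 6 of 13 fibroblast markers. With doublets kept, Fbn2 was among the 10 top genes of a fibroblast-like cluster with 2343 BDL cells. Serpina3n had a log2 ratio of 9.71 (8.96 to 10.58), Plat 6.06, Dclk1 5.87, Gda 5.39, Lox 5.198, Ncam1 5.19, Itih4 5.16 and Emp1 5.15. The lowest was Mup3, a major urinary protein gene of hepatocytes, at 0.206 against 51.1 CPM, log2 ratio -7.95, -8.71 to -7.29; in endothelial-like cells it stood at 0.585 against 53.1 CPM. Fabp1, another hepatocyte gene, stood at -3.21 and the glucagon receptor Gcgr at -3.75. Since Oil had no named hepatocyte class, the limit on genes higher in another class could not leave out hepatocyte genes there. Epor (-3.39), Vipr1 (-3.28), Angptl6 (-3.02), Tmem56 (-2.97), Adcy5 (-2.87), Bmp10 (-2.81), Mest (-2.78), Igfbp3 (-2.75) and the heat shock gene Hspa1b (-2.98) were also among the 12 lowest.

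Of 21 retinoid storage and quiescence genes, 15 were at least 2-fold lower and 0 higher (median log2 -1.15, -1.498 to -0.87, below all random lists; -0.94 without class markers). Of 27 fibrillar collagen and interstitial matrix genes, 17 were higher and 0 lower (median log2 1.72, 0.45 to 3.42, above all random lists), with Col3a1 at 2.78 and the tenascin Tnc at 3.42. The chemokine and inflammatory list had 19 of 28 higher and 1 lower (median log2 2.08, 0.98 to 3.76, above all random lists), with Ccl7 at 4.35, the neutrophil chemokine Cxcl1 at 2.89 and Cxcl10 at 2.08. The cell cycle list had 22 of 26 higher (median log2 2.87, 1.82 to 3.10, above all random lists), with Mki67 at 41.6 against 6.36 CPM and the mitotic kinase Cdk1 at 2.75. Contractile genes had 10 of 20 higher (median log2 0.96, 0.09 to 1.82, percentile 99.99), with Tagln at 2.68. The S100, annexin and intermediate filament list had 8 of 15 higher (median log2 1.16, 0.54 to 2.36, above all random lists), with S100a6 at 5.10 and Lgals1 at 3.31.

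Cholesterol synthesis genes had 12 of 18 at least 2-fold higher and 0 lower (median log2 1.35, 0.58 to 2.23, above all random lists), none of whose genes passed the limits for naming single genes. Oxidative and xenobiotic defence genes had 8 of 21 higher and 2 lower (median log2 0.78, -0.18 to 1.14, above all random lists), with the metallothioneins Mt2 at 3.92 and Mt1 at 3.07. Crosslinking and turnover genes had 10 of 23 higher and 1 lower (median log2 0.85, 0.33 to 1.37, above all random lists). Basement membrane genes had 5 of 15 higher (median log2 0.55, -0.30 to 1.22, percentile 99.1), TGF-beta and YAP targets 5 of 16 higher and 1 lower (median log2 0.71, -0.06 to 1.68, above all random lists) and glycolysis genes 4 of 14 higher (median log2 0.73, 0.02 to 1.15, percentile 99.98). Interferon response genes had 5 of 24 higher (median log2 0.27, -0.05 to 0.79, percentile 97.6), with Irf7 at 2.75. Dissociation and heat stress genes had 8 of 23 lower and 1 higher (median log2 -0.49, -1.34 to -0.06, percentile 1.09), with Fos at -2.15; the list stood at -0.58 in endothelial-like and -0.88 in cholangiocyte-like cells. ER secretory genes had 4 of 21 higher and 0 lower (median log2 0.04, -0.26 to 0.53, percentile 58.3).

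The portal fibroblast list, 13 of whose 19 measured genes named classes, had 13 higher and 1 lower (median log2 3.58, 0.10 to 4.16, above all random lists; 1.52 without them), with Ly6a at 3.95. Growth factors and receptors had 7 of 31 higher and 9 lower (median log2 -0.24, -0.998 to 0.25, percentile 18.5). Hgf stood at -1.09. The pericentral and periportal HSC lists had medians of 0.44 (-1.01 to 1.91, percentile 93.1) and -0.50 (-2.75 to 2.68, percentile 10.2). Of 99 named genes, 15 moved by over 1.5 times under an alternative and 4 near 0 (Smoc2, Ntf3, Pdgfrb and Des) changed sign. Cfd ranged from 6.98 to 10.17 over the alternatives. With fibroblast-like and smooth muscle-like cells added, Acta2 stood at 3.61, S100a6 at 3.82, Fbn2 at 6.87 and the portal fibroblast median at 2.26, which was 1.95 with free RNA subtracted.

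The comparison of BDL with CCL4 sets the 2 injuries side by side. Contractile genes were lower in BDL, with Acta2 at 835 against 3456 CPM, log2 ratio -2.05, -2.06 to -2.04 and Tagln at 1807 against 5314 CPM, log2 ratio -1.56, -1.56 to -1.55. Chemokine genes were higher, with Ccl2 at 750.2 against 145 CPM, log2 ratio 2.37, 2.35 to 2.40. Cluster 7 held 50264 of the 65482 Ccl2 UMIs of BDL HSC-like cells, while cluster 1 had Ccl2 at 156.8 CPM. Lrat was also higher in BDL, at 1443 against 602 CPM, log2 ratio 1.26, 1.25 to 1.28. Timp1 stood at 1606 against 1252 CPM and Col3a1 at 6649.9 against 7296 CPM, log2 ratios of 0.36 and -0.13.

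The genes with the highest ratios were Cfd, at 56.5 against 0.0880 CPM, log2 ratio 9.33, 8.40 to 10.46, the acute phase gene Itih4 (3.82), Serpina3f (3.60), Hhip (2.72), Ankrd55 (2.71), complement factor B, Cfb (2.63), Gja4 (2.59), the alarmin Il33 (2.21), Tnfrsf21 (2.20), Mt2 (2.20) and Procr (2.09). The lowest were the heat shock gene Hsph1 (-3.40), the growth factor midkine, Mdk (-2.78), Fos (-2.66), Nrep (-2.61), Igf1 (-2.57), Fosb (-2.51), Fam180a (-2.45), Cthrc1 (-2.06), Hspa1b (-2.04), Tnc (-2.00) and Tcim (-1.88).

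Of 20 contractile genes, 6 were at least 2-fold lower in BDL and 0 higher (median log2 -0.79, -1.01 to -0.58, below all random lists), with Myl9 at -1.67. Of 28 chemokine and inflammatory genes, 12 were higher and 0 lower (median log2 0.76, 0.65 to 1.5002, above all random lists), with Cxcl1 at 2.06 and the adhesion molecule Icam1 at 1.56. Of 21 retinoid storage and quiescence genes, 7 were higher and 0 lower (median log2 0.72, 0.31 to 1.19, above all random lists; 0.36 without class markers). Dissociation and heat stress genes had 14 of 23 lower and 0 higher (median log2 -1.33, -1.75 to -0.79, below all random lists), and stood at -1.54, -1.08, -1.15 and -1.24 in endothelial-, macrophage-, mesothelial- and cholangiocyte-like cells. ER secretory genes had 7 of 21 lower (median log2 -0.65, -1.04 to -0.48, below all random lists), with the chaperone Hspa5 at -1.43, and stood at -0.60, -0.76, -0.36 and -0.79 in the same other classes. The cell cycle list had 14 of 26 higher and 1 lower (median log2 1.21, -0.20 to 1.79, above all random lists), with Mki67 at 1.61 and Pcna, a replication gene, at -0.32. Its median was 0.43 with cells thinned to 2000 UMIs and 0.54 as a mean over cells; cluster 15 held 2.08% of the BDL and 2.002% of the CCL4 cells, at median depths of 19216 and 13979 UMIs.

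Fibrillar collagen and interstitial matrix genes had 2 of 27 higher and 4 lower (median log2 -0.33, -0.82 to 0.24, percentile 0.05), with Col1a1 at -0.91. Crosslinking and turnover genes had 5 of 23 lower (median log2 -0.20, -0.67 to 0.07, percentile 2.73), with the collagen chaperone Serpinh1 at -1.36. Cholesterol synthesis genes had 7 of 18 higher (median log2 0.87, 0.46 to 1.16, above all random lists), oxidative and xenobiotic defence genes 7 of 22 higher and 1 lower (median log2 0.65, -0.11 to 1.13, above all random lists), and interferon response genes 4 of 24 higher (median log2 0.52, -0.03 to 0.89, above all random lists), with H2-D1 at 1.19. Growth factors and receptors had 7 of 31 higher and 1 lower (median log2 0.22, -0.05 to 0.73, percentile 98.7), with the angiotensin receptor Agtr1a at 1.89. Glycolysis genes had 1 of 14 lower (median log2 -0.32, -0.61 to 0.29, percentile 0.26). The remaining lists were those of basement membrane (median log2 -0.10, -0.33 to 0.23, percentile 18.4), S100, annexin and intermediate filament (median log2 -0.18, -0.79 to 0.00, percentile 11.6), TGF-beta and YAP targets (median log2 -0.11, -0.72 to 0.41, percentile 11.2), portal fibroblast (median log2 0.04, -0.89 to 0.92, percentile 45.9), pericentral HSC (median log2 0.57, -1.40 to 1.03, percentile 99.4) and periportal HSC genes (median log2 0.22, -1.56 to 1.53, percentile 84.6).

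At resolution 1.5, where most cells of CCL4 cluster 2 left the HSC-like class along with other changes of names, Col1a1 stood at 0.03, S100a6 at 0.31 against -0.79, Lox at 0.59 against -0.20, Cthrc1 at -0.28, Igf1 at -1.07, Ccl2 at 1.62, Mki67 at 0.63, the fibrillar collagen median, turned, at 0.13 and the cell cycle median at 0.31, while Acta2 kept a range of -2.51 to -1.87 and Tagln of -1.76 to -1.48 over all alternatives. Of 98 named genes, 33 moved by over 1.5 times and 12 changed sign, among them Gas6, a ligand of Axl, at -0.60, which stood at 1.22 at resolution 1.5 and ranged from -2.41 with free RNA subtracted to 2.56 with fibroblast-like and smooth muscle-like cells added; Cfd ranged from 5.63 to 9.38. Lists near 0 turned as well: over the alternatives the basement membrane median ranged from -0.20 to 0.05, TGF-beta and YAP targets from -0.21 to 0.08, portal fibroblast genes from -0.40 to 1.06 and periportal HSC genes from -0.40 to 0.75. The fibrillar collagen median also turned, to 0.03, with fibroblast-like and smooth muscle-like cells added.

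**Figure D2:**
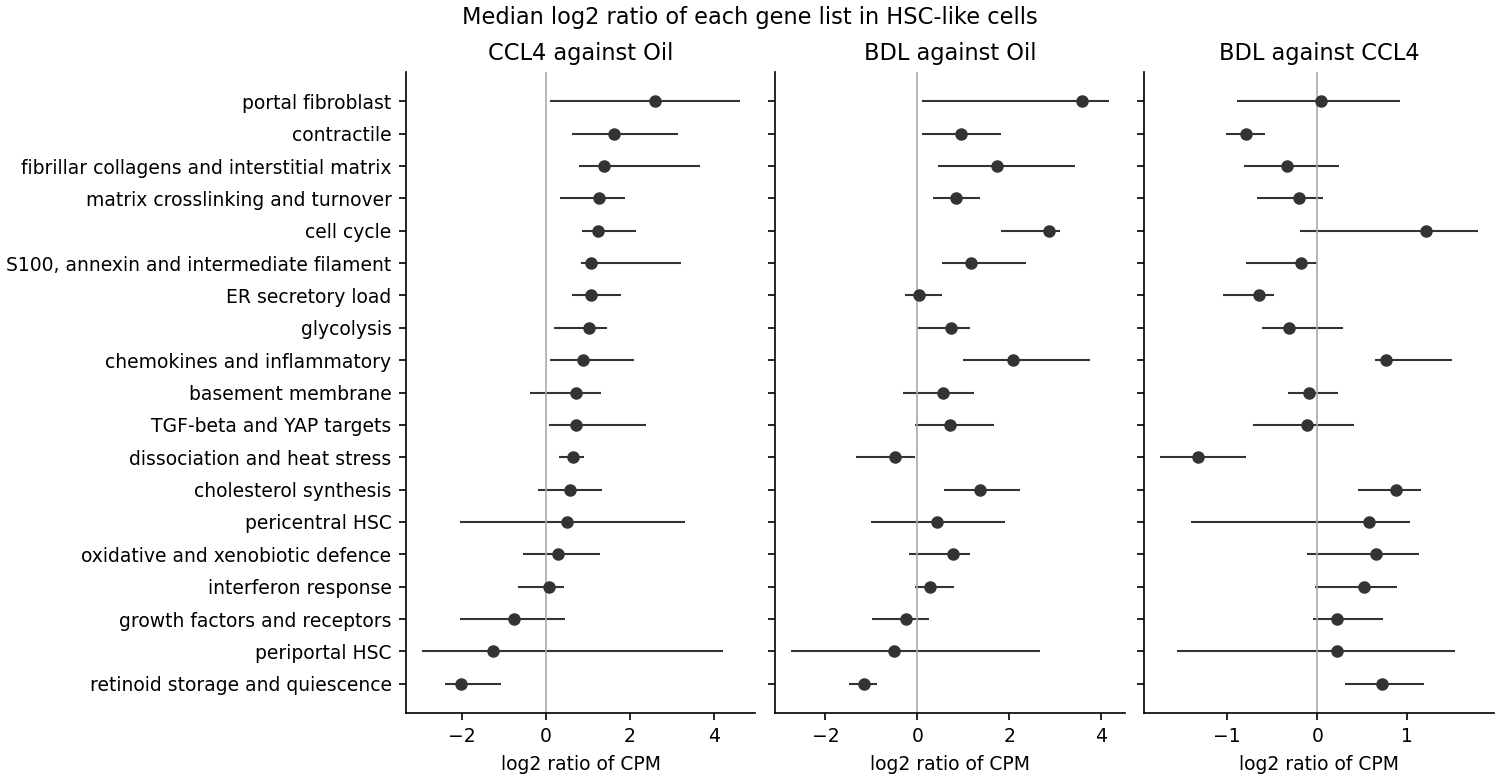
Median log2 ratio of CPM of each of the 19 gene lists in HSC-like cells, in 3 panels for the 3 comparisons, with the interval of the median over list members as bars. The contractile median is 1.62 for CCL4 against Oil, 0.96 for BDL against Oil and -0.79 for BDL against CCL4, and the chemokine median is 0.87, 2.08 and 0.76.

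To compare cells and not sums, each cell was thinned to 2000 UMIs, which left out 204, 368 and 105 HSC-like and 769, 447 and 818 endothelial-like cells of Oil, CCL4 and BDL. Acta2 was seen in 1.46% of the Oil HSC-like cells (1.17 to 1.80), 80.0% of those of CCL4 (79.2 to 80.8) and 27.2% of those of BDL (26.2 to 28.1). Endothelial-like cells, which should lack Acta2 apart from free RNA in the droplets, had it in 0.661%, 31.8% and 9.53%. Col1a1 was seen in 16.6%, 92.8% and 83.6% of HSC-like cells and in 0.992%, 49.8% and 25.01% of endothelial-like cells. Timp1 was seen in 0.543%, 64.8% and 49.1% of HSC-like cells, against 0.283%, 15.1% and 15.2%. Lrat was seen in 97.8%, 62.8% and 85.6%, against 9.31%, 6.46% and 9.69%. Mki67 was seen in 0.357%, 1.55% and 2.58% of HSC-like cells (0.771%, 4.40% and 6.04% unthinned), against 1.70%, 4.48% and 1.58% of endothelial-like cells, which can divide themselves. Without thinning, the HSC-like shares were 2.87%, 89.99% and 45.4% for Acta2, 30.8%, 97.5% and 96.2% for Col1a1, 1.67%, 83.1% and 75.5% for Timp1 and 99.3%, 90.3% and 96.9% for Lrat. The median depth was 5777.5, 9224.5 and 8676 UMIs in HSC-like and 2710.5, 2613 and 3278 in endothelial-like cells. The Oil clusters and the CCL4 and BDL clusters behind these shares were different ones, as given above.

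The share of 8 collagen genes in the UMIs of each thinned HSC-like cell had a median of 0.25% in Oil, 1.9% in CCL4 (1.9 to 1.95) and 1.0% in BDL (0.95 to 1.0). The whole distribution lay higher in both injured libraries. The 95th percentile of Oil, 0.65%, was exceeded by 83.8% of the CCL4 cells (83.0 to 84.5) and 68.0% of the BDL cells (67.0 to 69.0), against 3.99% in Oil. The 10th to 90th percentile range was 0.10% to 0.50% in Oil, 0.55% to 3.95% in CCL4 and 0.35% to 2.9% in BDL. Fibroblast-like cells of BDL had a median of 2.8% and the cells of CCL4 cluster 6 one of 2.65%, while endothelial-like cells had 0%, 0.15% and 0.10%. At resolution 1.5 the CCL4 median of HSC-like cells was 1.03%.

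**Figure D3:**
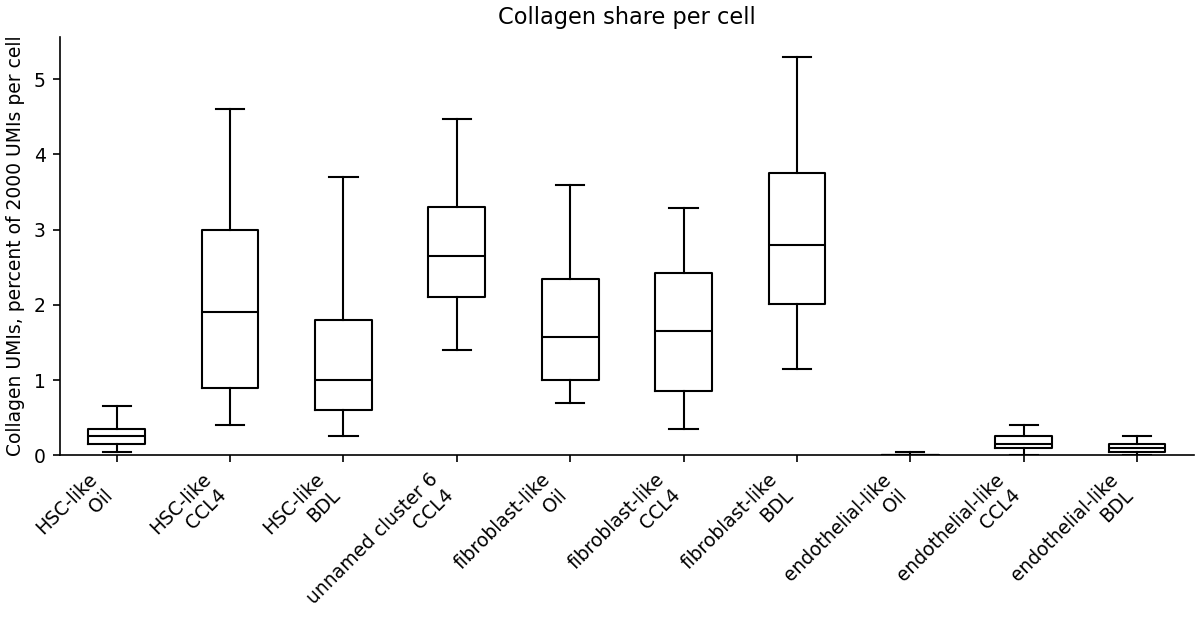
Collagen UMIs in percent of the 2000 UMIs kept per cell, by class and library: the box spans the quartiles with the median as a line, and the whiskers reach the 5th and 95th percentiles of cells. The HSC-like medians are 0.25% in Oil, 1.9% in CCL4 and 1.0% in BDL.

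The series asks for the origin of myofibroblasts, so the UMIs of matrix and contractile genes were assigned to classes. HSC-like cells held 45.2% of the Col1a1 UMIs of Oil, 68.3% of those of CCL4 and 61.4% of those of BDL. The next holder was the mesothelial-like class in Oil (19.7%), cluster 6 in CCL4 (27.5%) and the fibroblast-like class in BDL (33.9%, 33.7 to 34.0). Col3a1 UMIs lay in HSC-like cells to 72.7%, 75.5% and 68.8%, Lox UMIs to 44.7%, 73.6% and 63.1%, and Postn UMIs to 91.7%, 87.4% and 73.9%. Acta2 UMIs of Oil were mostly in the 28 smooth muscle-like cells (59.5%) and less in HSC-like cells (27.8%), while HSC-like cells held 79.0% in CCL4 and 72.9% in BDL. Timp1 UMIs of Oil were mostly in mesothelial-like cells (84.0%), and in HSC-like cells to 78.9% in CCL4 and 83.8% in BDL. These shares depend on which cells the isolation captured and on the names: at resolution 1.5 the HSC-like share of Col1a1 in CCL4 was 16.5%, and with doublets kept that in BDL was 36.8%.

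Within BDL, fibroblast-like cells (1576 cells, 92.1% of them in cluster 10) had more collagen UMIs than HSC-like cells. Col1a1 had a log2 ratio of 1.30 (1.29 to 1.31), Col1a2 1.17, Col3a1 0.74 and Lox 1.16. S100a6 stood at 2822 against 441 CPM and Gas6 at 2472 against 51.5 CPM, log2 ratios of 2.68 and 5.58. Acta2 (-0.64), Tagln (-0.92) and Timp1 (-0.62) were lower. Mki67 stood at 1.89 CPM, and in the HSC-like clusters 1, 7 and 14 at 1.85, 2.53 and 5.39 CPM; the cycling cluster 15, which went to the HSC-like class, had 440.3 CPM. Of 24 measured fibrillar collagen and interstitial matrix genes that named no class, 10 were at least 2-fold higher and 2 lower (median log2 0.85). The interferon list had a median of -0.81 with 9 of 24 lower, and the contractile list one of -0.56. The collagen difference did not hold for every BDL HSC-like cluster. Cluster 14 had a median collagen share of 2.65%, against 2.85% and 2.525% in fibroblast-like clusters 10 and 29. Clusters 1, 7 and 15 had 0.8%, 1.0% and 1.75%. Lox stood at 394.1 CPM in cluster 14 and at 384.5 and 728.6 CPM in clusters 10 and 29. In Oil, with 64 fibroblast-like cells, Col1a1 stood at 4.67 (4.60 to 4.75), Timp1 at 3.71, Acta2 at 1.28 and Postn at -1.43. The 47 fibroblast-like cells of CCL4 were under the minimum of 50 and were not compared.

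The features included 7 fluorescent proteins, of which EGFP and tdTomato had UMIs; both were chosen after their values were seen. EGFP stood at 1766 CPM in Oil, 796 in CCL4 and 1144 in BDL HSC-like cells, and was seen in 94.1%, 75.3% and 83.4% of them after thinning (97.5%, 96.2% and 97.1% without). Endothelial-like cells had it in 4.68%, 4.38% and 5.29% after thinning (6.65%, 8.67% and 8.93% without), at the depths given above. Fibroblast-like cells of BDL had it in 14.0% (12.4 to 15.9; 41.0% without thinning, median depth 12070.5 UMIs, 2 cells left out). Cluster 6 of CCL4 had it in 54.7% (52.8 to 56.7; 91.2% without thinning, median depth 10279 UMIs, 9 cells left out). Smooth muscle-like cells had it in 58.3%, 55.2% and 60.3% of 24, 29 and 136 thinned cells. Which promoter drives EGFP was not given in the sources used here, so these values do not state descent.

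**Figure D4:**
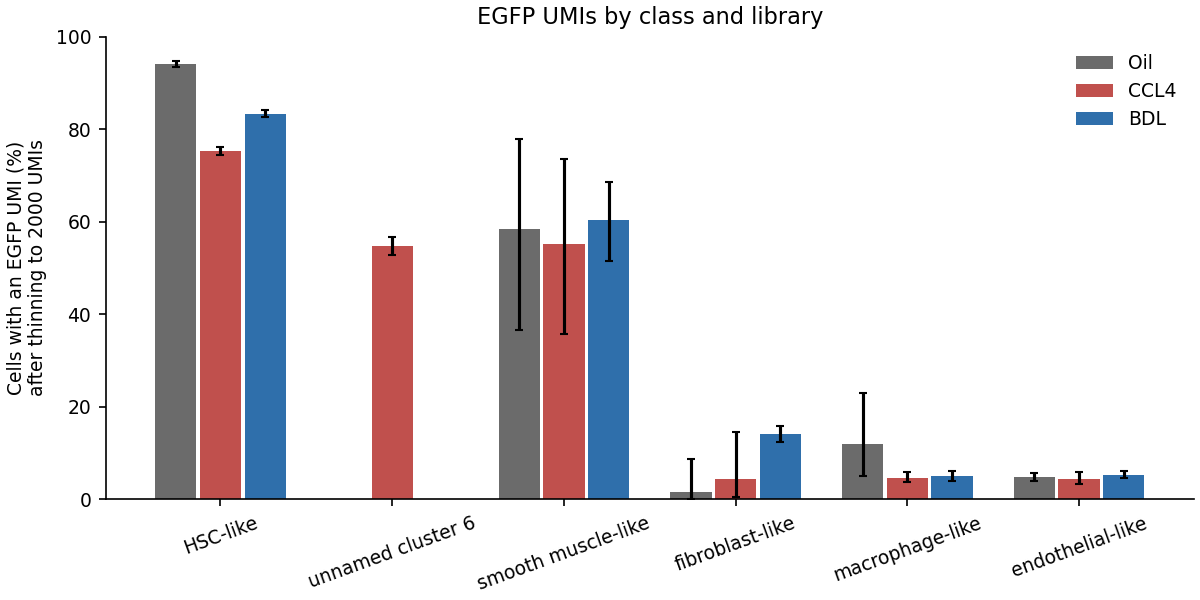
Share of cells with an EGFP UMI after thinning to 2000 UMIs, in percent, by class and library, with Clopper-Pearson 95% intervals as bars. HSC-like cells stand at 94.1%, 75.3% and 83.4% in Oil, CCL4 and BDL, cluster 6 of CCL4 at 54.7% and BDL fibroblast-like cells at 14.0%.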

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

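Of the tests in this part, all but the one for doublets with macrophages were chosen after the result was seen. Dissociation and heat stress genes in HSC-like cells were higher in CCL4 than in Oil (median log2 0.65) and lower in BDL than in Oil (-0.49), opposite directions that were not tested against each other; between BDL and CCL4 the median was -1.33. The pattern does not rest on cells with over 10% mitochondrial UMIs, since the stricter filter, which leaves them out, gave -1.35. Damaged cells as a cause are not decided by this, since that filter moved no list median by more than 0.0651. Damage in cells under that limit was not tested. A response of HSC-like cells alone is argued against, since the endothelial-like cells reached -1.54. Handling that differed between the libraries, such as time in the digestion, may account for the pattern, since every one of the 4 other classes examined had a median of -1.08 or lower. With 1 library per group it stays open whether the injury itself reached all classes.

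In the features outside the comparisons, tdTomato stood at 27.0 CPM in CCL4 and 35.5 CPM in BDL HSC-like cells, above 20.7 CPM in Oil. Over 20% mitochondrial UMIs left out 21.6% of the BDL barcodes, against 8.48% of those of Oil.

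EGFP UMIs appeared in 54.7% of the thinned cells of cluster 6, the CCL4 cells with matrix genes but too few HSC markers to be named. Free RNA is argued against, since endothelial-like cells of that library had it in 4.38% and macrophage-like cells in 4.61%. Randomly loaded doublets of HSC-like and fibroblast-like cells as the whole cluster are argued against. They would come with doublets of these 2 classes with other classes, if such doublets were called or clustered apart. Called doublets and cells of mixed clusters in the main clustering together numbered 1974. This leaves out a mixed cluster of 383 CCL4 cells at resolution 1.5. Under either of 2 namings the doublets needed were at least 3.29 times those 1974. Pairs of cells that stuck together were not tested by this, and 2 other tests did not decide: depth, with a median of 10279 UMIs against 9224.5 in HSC-like cells of CCL4, since clusters mixed of HSC-like and other cells (at least 20 cells in the library) lay near the HSC-like cells too, at 10141.5 in CCL4 (cluster 35), 5809 and 6872 against 5777.5 in Oil (27 and 31) and 8671, 8030, 8091 and 7849 against 8676 in BDL (27, 33, 36 and 39); and genes at least 2-fold above every parent cluster, with 1.09% of genes under the names used and 0.331% at resolution 1.5 against up to 0.302% in mixed clusters. Descent from HSC-like cells stays open and cannot be told apart from EGFP made in other mesenchymal cells, since 55.2% of the smooth muscle-like cells of the library also had EGFP UMIs and the construct was not given in the sources used here.

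Chemokine and inflammatory genes stood higher in BDL than in CCL4 HSC-like cells (median log2 0.76). For Ccl2 and Cxcl1 this rested largely on cluster 7. With 2271 of the 8875 BDL HSC-like cells, it held 50264 of 65482 Ccl2 and 10507 of 12798 Cxcl1 UMIs. Cluster 1, with 5103 cells, had these genes at 156.8 and 33.39 CPM, against 145.0 and 35.07 CPM in CCL4 HSC-like cells. Clusters 14 and 15 had Ccl2 at 291.1 and 591.1 CPM and Cxcl1 at 36.36 and 59.19 CPM. The list median is not given per cluster. Free RNA is argued against, since with it subtracted the median was 0.92. Doublets with macrophages are argued against: of 2313 BDL cells with a Ccl2 UMI 5.97% had a C1qa UMI, and of 6457 without 5.84%, a ratio of 1.02. Dissociation stress that raises both lists together is argued against, since the stress list had a median of -1.33 in the opposite direction. A response to the bile duct ligation may account for the pattern as a hypothesis, found and weighed in the same single libraries. Other differences in handling between the libraries were not tested for the chemokine list and stay open as well. Strain and animal effects were not tested.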

How the results depend on the processing

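Adding cluster 6 to the HSC-like cells was chosen only after the result was seen; the other settings were fixed before the data were examined. Of 570 alternative list medians 558 kept their sign and 12 changed it, and of 2588 alternative gene ratios 2561 kept and 27 changed it. As reversed count only changes of sign of gene ratios of at least 2-fold, of list medians of at least 0.5, and of the retinoid, fibrillar collagen, contractile and chemokine medians, 3 list medians and 3 gene ratios; the other changes of sign were of smaller values, such as Gas6, S100a6, Lox and Col1a1 in BDL against CCL4 at resolution 1.5. Single genes moved by a median of at most 0.20 under any setting. No paired analysis was possible because each group has 1 library. Resolution 1.5 reversed the pericentral list in CCL4 against Oil (-0.16) and, in BDL against CCL4, the fibrillar collagen list (0.13), Ltbp2 (0.12) and Dpt (0.0456). Adding fibroblast-like and smooth muscle-like cells reversed, in BDL against CCL4, the fibrillar collagen list (0.0329) and Fbln2 (0.0627). In the order Oil, CCL4, BDL, the stricter filter gave HSC-like shares of 58.7%, 54.6% and 54.8% and a BDL fibroblast-like share of 9.88%. Doublets kept gave 51.1%, 52.3% and 37.2%, with fibroblast-like shares of 10.2% in CCL4 and 12.6% in BDL. Resolution 1.5 gave 53.7%, 28.7% and 45.7%, with 35.8% fibroblast-like cells in CCL4. Shares of HSC-like cells with Acta2 were 2.87%, 89.99% and 45.4% unthinned and 2.33%, 88.1% and 36.1% at 4000 UMIs; they were 81.1% (CCL4, stricter filter), 72.1% (CCL4, resolution 1.5) and 23.2% (BDL, doublets kept). Those with Col1a1 were 30.8%, 97.5% and 96.2% unthinned and 24.2%, 97.5% and 92.6% at 4000 UMIs; they were 15.6% (Oil, stricter filter), 87.1% (CCL4, resolution 1.5) and 81.7% (BDL, doublets kept). The collagen median was 0.255% in Oil unthinned, 2.0% (CCL4) and 0.90% (BDL) with doublets kept, and 1.03% in CCL4 at resolution 1.5. HSC-like cells held 42.2%, 68.4% and 62.2% of Col1a1 UMIs under the stricter filter, 39.7%, 68.0% and 36.8% with doublets kept, and 44.1%, 16.5% and 59.9% at resolution 1.5. That unthinned and deeper cells show more shares with a UMI follows from their depth; for the other values the cause was not tested. Depth limits single genes near 3 UMIs of Oil, where 1 UMI is 0.0282 CPM.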

Other observations

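No explanation is tested in this part, and its genes and classes were chosen after their values were seen. Other classes also differed between libraries, but the clusters that made up a class differed in kind or share between libraries, so these values compare different mixtures of clusters. Cluster 18, with Arg1 among its top genes, held 37.1% of the macrophage-like cells of CCL4 and 2.05% of those of BDL, and cluster 8 held 39.1% and 80.0%. Cholangiocyte-like cells lay mainly in cluster 12 in Oil, 16 in CCL4 and 22 in BDL, and endothelial-like cells in clusters 5, 11 and 3. Cholangiocyte-like cells, the cells lining bile ducts, had more chemokine UMIs in BDL than in Oil, with Ccl2 at 1115 against 12.3 CPM, the neutrophil chemokine Cxcl5 at 476 against 9.06 CPM and the ubiquitin-like gene Ubd at 518 against 2.24 CPM; 18 of 22 measured chemokine and inflammatory genes were at least 2-fold higher (median log2 2.82). Endothelial-like cells of BDL had more of the leukocyte adhesion gene Selp (205 against 6.22 CPM) and of Lrg1 (489.7 against 20.5 CPM) than those of Oil. Macrophage-like cells of BDL had less Arg1, arginase 1 (65.5 against 1167 CPM), and less fibronectin, Fn1 (110.2 against 3096 CPM), than those of CCL4, and more of the chemokines Ccl8 (635 against 13.2 CPM) and Cxcl10 (199.5 against 16.1 CPM).

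Interferon response genes were higher in BDL than in CCL4 by a median log2 of 1.28 in macrophage-like cells (16 of 24 at least 2-fold higher), 1.15 in mesothelial-like cells (14 of 23) and 1.56 in cholangiocyte-like cells (15 of 23), against 0.52 in HSC-like cells and 0.25 in endothelial-like cells (0 of 24). Cell cycle genes were higher in BDL than in CCL4 cholangiocyte-like cells (median log2 1.16) and lower in endothelial-like cells (-0.70).

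Ifi202b had 0 UMIs in every class of Oil, among 59845106 UMIs of kept cells, with an upper limit of 0.0616 CPM. In CCL4 it stood at 33.8 CPM in endothelial-like, 49.9 in macrophage-like and 78.0 in mesothelial-like cells, and in BDL at 29.7, 99.99 and 116 CPM. The Y-linked gene Ddx3y stood at 113, 75.9 and 85.5 CPM over the kept cells of Oil, CCL4 and BDL, and Xist had 6, 12 and 11 UMIs. The strain of the animals was not given in the sources used here.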
